A study of Rattus norvegicus with 6 samples.

How the data were processed

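Lung RNA of 6 adult male rats was measured on 1-colour arrays, 3 from normal rats and 3 from rats with acute respiratory distress syndrome (ARDS) brought on by lipopolysaccharide, a component of the outer membrane of Gram-negative bacteria. Per the labels' protocols, total RNA was first digested with RNase R, an exonuclease that removes linear RNA and leaves most circular RNA (circRNA, formed when the ends of an exon or exons are joined back to back). The remaining RNA was amplified by random priming, labelled with the dye Cy3 and hybridised to a commercial rat circRNA array. The labels number the animals separately, so each array was taken as 1 rat.

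The spots were read with Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. The processed signal used here is an intensity that, per the file headers, was background-subtracted and spatially detrended within each array, with no scaling between arrays. The deposited table of the whole series holds log2 values made by the authors, for which the submitters' processing notes name limma without its version. Set against the scanner values, that table was on a log2 scale and not centred by gene and, once the columns of some probes were exchanged, close to a quantile normalization. Its direction is taken up in the closing section. The median of its columns was 5.97, 6.04 and 6.03 for normal replicates 1 to 3 and 6.5, 6.44 and 6.43 for ARDS replicates 1 to 3. It was used only as an alternative.

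Each array held 15165 spots that were not controls. These comprised 14145 circRNA probes, 62 probes for linear transcripts with 10 spots each, and 20 custom probes of unstated purpose, which were not used. Control spots and spots marked as outliers, 30 to 64 per array, were left out, and spots of 1 probe were averaged. No spot was saturated. The log2 processed signal minus the array's 75th percentile over the circRNA probes gave the scaled value. Probes well above background on at least 3 of the 6 arrays were tested, whatever the group, which left 13245 circRNA probes and 51 linear probes. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Single values per array were compared by a two-sided exact permutation test, which with 3 arrays against 3 cannot give a p below 0.1. The number of arrays limits the precision of every value.

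The comparison, its test, the filter, the rule for naming circRNAs and most alternatives were fixed before the data were examined. The rule took the 12 circRNAs with the largest increase and the 12 with the largest decrease among those past the threshold, above background on all 6 arrays and with groups that did not overlap. It further took up to 3 per direction that could be given only as bounds. The files do not pair the circRNA probe numbers with circRNA names, host genes or positions, so only 2 probes that rose and 2 that fell are named, and the others are summarised. For the same reason the planned tests of host gene lists, of cell type markers, of circRNAs sharing a host gene and of circRNA classes were not run, and what these circRNAs are is not analysed here. No columns of other samples were present (0 columns).

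Linear transcripts were added to the comparison after the files had been opened. They were selected by their probe identifiers, not by their values, and were tested in one fit together with the circRNA probes. Of the 62 linear probes, 39 matched a symbol by accession in a RefSeq gene table of the GRCr8 assembly and 23 did not. The 39 matched probes stand for 38 symbols, Ldha having 2 probes, and each probe was kept separate.

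The alternatives were quantile normalization, the array median, no scaling, a normexp background correction with an offset of 50 followed by quantile normalization, other filters, a trended and robust variance, array weights, blocks, each array left out, and a fold of at least 2 with an unadjusted p. The normexp setting had been planned on the mean signal and was run on the median signal, the column that the scanner files hold. All files give the scan, in which ARDS replicate 3 stood alone, and the scan took the place of the slide as a block. The procedure was tested on simulated data in which 200 of 13245 circRNA probes were changed, in 10 simulations of the ARDS against normal comparison. It recovered 3.3% of those changed 2-fold and 58.3% of those changed 4-fold, and 4.64% of its calls were false. The simulated noise was drawn separately for each probe and array, and far fewer probes were changed than the 2604 called in the data. These percentages therefore hold for the simulated setting and need not hold for the real comparison.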

Results

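The study profiled circRNAs in lungs of rats with lipopolysaccharide-induced ARDS, a model of acute inflammatory lung injury, against lungs of normal rats, with 3 arrays per group. The comparison asks which circRNAs differ in level between injured and normal lung. Of the 14145 circRNA probes, 13425, 13200 and 13223 were well above background in normal replicates 1, 2 and 3. In ARDS replicates 1, 2 and 3, 12637, 12671 and 12179 were.

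The circRNAs of ARDS lung gave a dimmer signal and fewer of them were detected. The mean number above background was 13283 ± 124 (SD, n = 3) in normal and 12496 ± 275 (SD, n = 3) in ARDS lung, a difference of -787, and the groups did not overlap (exact permutation p = 0.1, the smallest that 3 against 3 allows). By the scanner's less strict flag for a positive and significant signal the difference was -146.7. There were 252 circRNA probes above background on all 3 normal arrays and on no ARDS array, and 0 with the opposite pattern. After scaling, 45 of these 252 passed the test as lower in ARDS. The 75th percentile of the log2 signal was 7.4 ± 0.182 (SD, n = 3) in normal and 6.16 ± 0.448 (SD, n = 3) in ARDS lung (exact permutation p = 0.1). The signal was also more concentrated, since the 100 brightest circRNA probes carried 39.4% ± 1.79 (SD, n = 3) of it in normal and 54.4% ± 3.3 (SD, n = 3) in ARDS lung (exact permutation p = 0.1). All changes below are relative to the 75th percentile of each array. Without any scaling the median difference of the tested circRNAs was -1.19 on the log2 scale, against 0.05 with it.

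**Figure D1:**
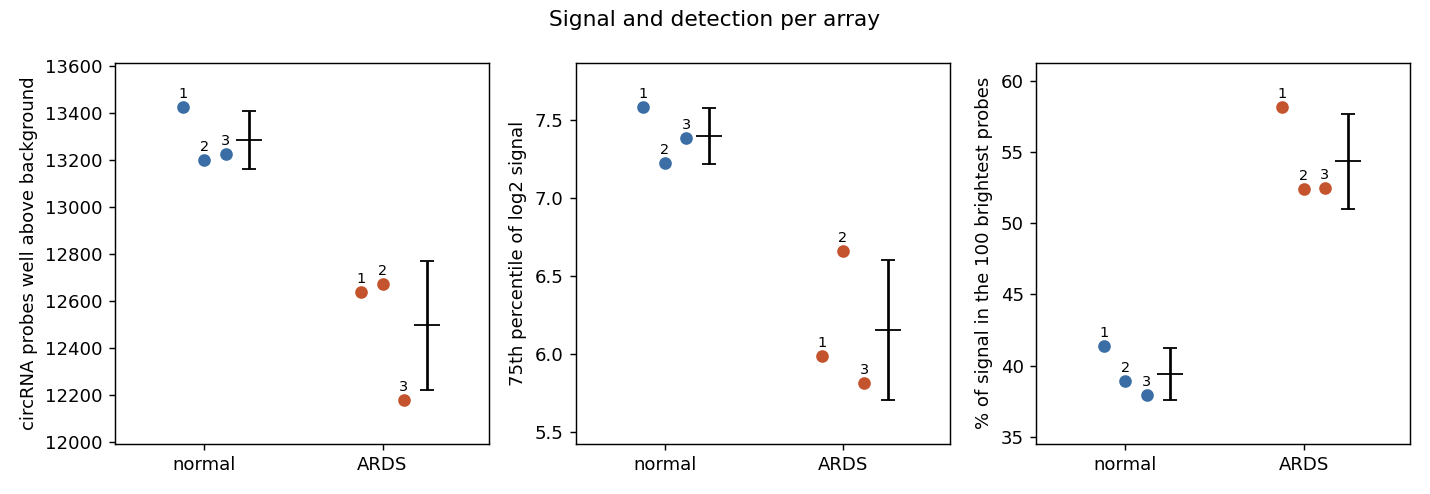
Values of each array (points, numbered by replicate) with the group mean and SD (black bars, n = 3): the number of circRNA probes well above background, the 75th percentile of the log2 signal, and the percentage of circRNA signal in the 100 brightest probes; the axes do not start at 0. In each panel the 3 ARDS arrays lie apart from the 3 normal arrays, with 12179 to 12671 against 13200 to 13425 probes above background.

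Many circRNAs changed in ARDS lung, in both directions. Of 13245 circRNAs tested, 2604 passed (19.7%), of which 1521 were higher and 1083 lower in ARDS lung (limma, Benjamini-Hochberg adjusted). The median change was 2.4-fold among those higher and 2.27-fold among those lower, or 2.26-fold without the 45 lower circRNAs that were not well above background on any ARDS array, whose change is only a bound. A change of at least 4-fold was seen for 71 circRNAs that rose and 86 that fell. The values of the groups did not overlap for any of the 2604 circRNAs, and did not overlap for 44.9% of all those tested. For any given circRNA chance gives 10%, but the circRNAs were measured on the same arrays and are not independent. The share under chance can therefore lie far from 10%, so no conclusion is drawn from the 44.9%.

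The 2 named circRNAs that rose were ASCRPR009085 and ASCRPR008416, the array's own identifiers. The scaled log2 value of ASCRPR009085 was -1.92 ± 0.21 (SD, n = 3) in normal and 3.67 ± 0.98 (SD, n = 3) in ARDS lung, a 48.3-fold increase (log2 5.59, SE 0.46, limma adjusted p = 0.00918). ASCRPR008416 went from 1.15 ± 0.19 to 6.46 ± 0.67 (SD, n = 3 each), a 39.8-fold increase (log2 5.31, SE 0.35, limma adjusted p = 0.0023, the lowest of all circRNAs tested). The 2 named circRNAs that fell were ASCRPR013687 and ASCRPR000006. ASCRPR013687 was at 2.17 ± 0.12 in normal and -1.16 ± 0.49 in ARDS lung (SD, n = 3 each), 10.1-fold lower (log2 -3.33, SE 0.29, limma adjusted p = 0.00966). ASCRPR000006 was at 3.35 ± 0.44 in normal and 0.03 ± 0.32 in ARDS lung (SD, n = 3 each), 10-fold lower (log2 -3.32, SE 0.3, limma adjusted p = 0.00977). All 4 were above background on all 6 arrays. Without normal replicate 2 or normal replicate 3, ASCRPR009085 (limma adjusted p = 0.0625 and 0.0612), ASCRPR013687 (0.0625 and 0.0846) and ASCRPR000006 (0.0625 and 0.0846) no longer passed. Their log2 differences in these fits were 5.629 and 5.475, -3.315 and -3.285, and -3.119 and -3.293. All 4 passed under every scaling, but the sizes moved: ASCRPR009085 was at log2 4.35 without scaling and 3.74 with normexp, ASCRPR008416 at 4.07 and 4.28, ASCRPR013687 at -4.58 and -2.53, and ASCRPR000006 at -4.57 and -3.04. The normexp offset of 50 draws differences that involve dim values toward 0. ASCRPR009085 had a mean signal of 44.6 in normal lung, and ASCRPR013687 one of 31.9 in ARDS lung. Among circRNAs above background on all 6 arrays, the 12 with the largest increase, these 2 included, rose between 8.27-fold and 48.3-fold, and the 12 with the largest decrease fell between 6.49-fold and 10.1-fold.

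**Figure D2:**
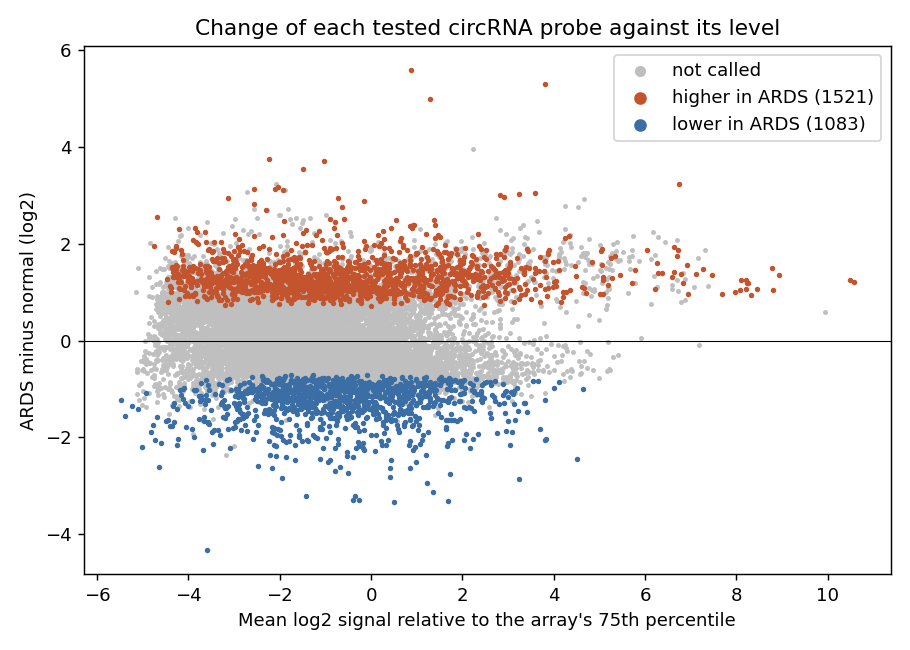
ARDS minus normal (log2, vertical) against the mean scaled log2 signal (horizontal) of each of the 13245 tested circRNA probes; orange probes were higher (1521) and blue probes lower (1083) in ARDS lung at an adjusted p under 0.05, and grey probes did not pass. At the bright end the probes that passed lie above 0.

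The calls were also counted by brightness, without a test between levels. Of the 133 circRNAs in the top 1% of mean signal, 48 passed, all of them higher in ARDS lung with this scaling, and their median scaled difference was 1.31. Relative to the median of the array, the median of these 133 was 6.43 ± 0.558 (SD, n = 3) in normal and 7.73 ± 1.01 (SD, n = 3) in ARDS lung, a difference not much larger than the spread between ARDS arrays. Between the 90th and 99th percentiles 260 were higher and 127 lower, with a median scaled difference of 0.05. Before scaling the median difference of the top 1% was 0.06, whereas it was -1.19 between the 90th and 99th percentiles, -1.41 between the 75th and 90th percentiles of signal, and -0.92 among the 3312 dimmest circRNAs. Of these dimmest circRNAs 335 were higher and 141 lower.

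Pearson's r between arrays over the tested circRNAs, which are not independent replicates, was 0.935 to 0.975 between normal arrays, 0.884 to 0.947 between ARDS arrays and 0.773 to 0.946 between groups. Normal replicate 1 correlated at 0.946 with ARDS replicate 2, and at 0.935 and 0.97 with normal replicates 2 and 3. The first principal component held 60.5% of the variance and parted the groups, with normal arrays at -21.2, -66.3 and -56 and ARDS arrays at 90.6, 35.3 and 17.7. The second held 24.1%, with ARDS replicate 3 apart at -68.9 and the other arrays between -14.1 and 36.6.

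The split into higher and lower circRNAs depended on the scaling. The share of calls that were higher was 58.4% here, 46.2% with quantile normalization (1154 higher, 1346 lower), 42.1% with normexp and quantile normalization (828 higher, 1140 lower) and 0.422% with no scaling (33 higher, 7787 lower). Calls made in the same direction under the percentile, median, quantile and normexp settings numbered 1564, of which 709 were higher and 855 lower. The count also moved when 1 array was left out. It was 189 without normal replicate 1, 3 without normal replicate 2, 3 without normal replicate 3 and 401 without ARDS replicate 1. Without ARDS replicate 2 it was 3095. In the 4 fits with fewer calls 4639, 3858, 3298 and 4125 circRNAs had an unadjusted limma p under 0.05. With all arrays 5282 did. A fit with 1 array fewer also has less power, which was not told apart from reliance on single arrays. No called circRNA changed sign in the 4 fits with fewer calls, but none could, because the groups did not overlap for any called circRNA. ARDS replicate 3 was scanned apart from the other 5 arrays. A block for the scan therefore removes that array, and is nearly the same fit as leaving it out, not a second check. The count was 3632 with the scan as a block and 3637 within the first scan.

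The array also measures linear transcripts, some of which changed relative to circRNAs. Of 51 linear probes tested, 16 were higher and 2 lower in ARDS lung (limma, adjusted over all probes), and 21 were higher and 3 lower when adjusted over the list alone. The list was added after the files had been opened. The median scaled difference of the 51 probes was 0.55 on the log2 scale, against 0.05 for circRNAs, and without scaling it was -0.69. The linear probes were dim, their median lying at percentile 25.7 of the circRNA signal, and the 3312 dimmest circRNAs had a median scaled difference of 0.32. With no scaling 1 probe passed as higher and 17 as lower; Ptk2b, Cyp2e1 and Eif4b kept their direction and passed in both settings. RNase R digestion precedes the measurement, and these values are levels after it, not levels in the tissue.

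Nlrp3, the sensor protein of an inflammasome that matures interleukin-1β, rose 4.3-fold (log2 2.11, SE 0.27, limma adjusted p = 0.0134). Ptk2b, a calcium-responsive tyrosine kinase related to focal adhesion kinase, rose 8.1-fold (log2 3.02, SE 0.63, limma adjusted p = 0.0255). B2m, the light chain of MHC class I molecules, rose 2.37-fold (log2 1.25, SE 0.3, limma adjusted p = 0.0322). Nlrp3 was dim, with a mean signal of 8.35 in normal and 15.2 in ARDS lung, at percentile 12.8 of the circRNA signal. Ptk2b was at 10.7 and 36.7, whereas B2m was bright, at 998 and 1000. Without scaling Nlrp3 stood at 0.86 (limma adjusted p = 0.103), Ptk2b at 1.77 (0.0206) and B2m at 0.004 (0.995). With normexp they stood at 0.34 (limma adjusted p = 0.0418), 0.94 (0.115) and 0.86 (0.141), and B2m also missed the threshold with quantile normalization (0.114). The normexp offset of 50 draws the differences of dim probes toward 0. The smaller normexp sizes of Nlrp3 and Ptk2b are therefore no sign by themselves that these changes are unstable. The 2 transcripts that fell did so with and without scaling and with quantile, median and normexp settings: Cyp2e1, a cytochrome P450 that oxidises ethanol and other small molecules, fell 2.25-fold (log2 -1.17, SE 0.23, limma adjusted p = 0.024), and Eif4b, a translation initiation factor, fell 2.3-fold (log2 -1.2, SE 0.25, limma adjusted p = 0.0264). Without scaling they stood at -2.41 and -2.45, and with normexp, whose offset draws dim values together, at -0.47 and -0.72.

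Of the other linear probes with a symbol, 7 passed, all higher in ARDS lung with this scaling. Hprt1 of purine salvage rose 2.9-fold (log2 1.53, SE 0.28, limma adjusted p = 0.0215), Ppp2r2b, a regulatory subunit of protein phosphatase 2A, 2.91-fold and the microtubule-associated Map2 2.4-fold. These 3 no longer passed without scaling, at 0.29 (limma adjusted p = 0.424), 0.3 (0.448) and 0.02 (0.96), or with normexp, at 0.2 (0.106), 0.27 (0.0858) and 0.27 (0.0813). Their mean signals per group ran from 6.64 to 15.1, far below the normexp offset of 50, which makes their normexp sizes small. Gusb, a lysosomal glucuronidase, rose 2.27-fold, the ribosomal protein transcript Rplp1 2.12-fold and Pop7, of the RNase P complex, 1.98-fold, but these 3 lay below 0 without scaling, at -0.06, -0.16 and -0.26. Gusb and Pop7 were dim, at percentiles 17.2 and 16.9 of the circRNA signal, and Rplp1 was at 65.1. With normexp Rplp1 passed (limma adjusted p = 0.0323) and Gusb (0.128), Pop7 (0.146) and the custom probe for Ldha (0.0558) did not, and Pop7 also missed the threshold with quantile normalization (0.0658). With the scan as a block 16 linear probes passed, but not Gusb (limma adjusted p = 0.0541), Pop7 (0.0576) or the custom probe for Ldha (0.0635). Within the first scan, which is nearly the same fit, 16 passed too. Of the 2 probes for Ldha, lactate dehydrogenase A, the custom probe rose 2.03-fold (limma adjusted p = 0.0446; -0.22 without scaling) and the catalogue probe, at log2 0.52, did not pass (limma adjusted p = 0.148). Sdha, a subunit of succinate dehydrogenase, was at 1.6 (SE 0.48, limma adjusted p = 0.0521) and Pgk1, a glycolytic kinase, at 0.87 (SE 0.36, limma adjusted p = 0.118), and neither passed. Actb, the cytoskeletal actin, was at -0.54 (SE 0.25, limma adjusted p = 0.154), Hsp90ab1, a chaperone, at 0.55 (SE 0.26, limma adjusted p = 0.153) and Rpl13a, a ribosomal protein transcript, at -0.04 (SE 0.32, limma adjusted p = 0.929), none of which passed. The count of 18 fell to 2 without normal replicate 1, to 0 without normal replicate 2 or normal replicate 3, where 21 had an unadjusted p under 0.05 in limma, and to 4 without ARDS replicate 1, and it was 28 without ARDS replicate 2.

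**Figure D3:**
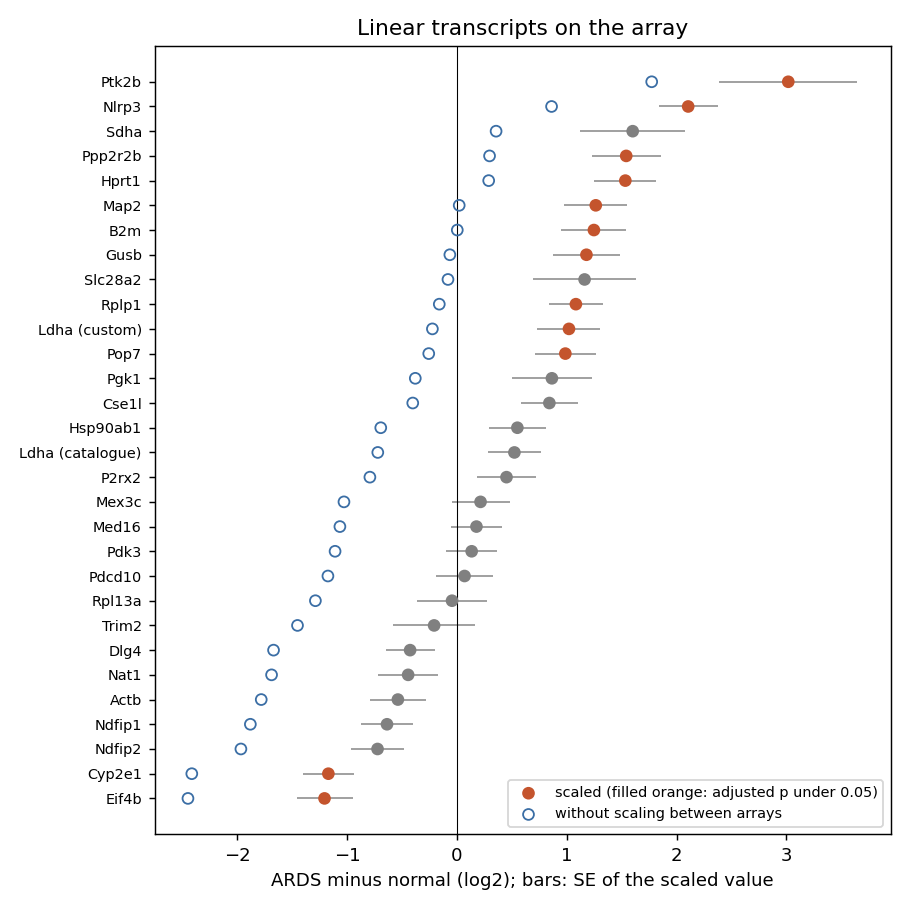
ARDS minus normal (log2, horizontal) of the 30 tested linear probes with a symbol (vertical): filled points are scaled values with their SE, orange where the adjusted p over all probes was under 0.05, and open circles are the differences without scaling. Scaled values run from -1.2 for Eif4b to 3.02 for Ptk2b. Among the probes that passed, Gusb, Rplp1, the custom Ldha probe and Pop7 lie above 0 with scaling and below it without, as do several that did not pass.

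The authors' deposited table gave another direction for the circRNAs that fell. It listed ASCRPR013687 at a mean of 6.21 in normal and 9.33 in ARDS columns, and ASCRPR000006 at 7.17 and 10.5, although the scanner values of both were lower on all 3 ARDS arrays. All 13438 probes of the authors' deposited table had a higher mean in the ARDS columns (100%). The directions given above come from the scanner files.

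**Figure D4:**
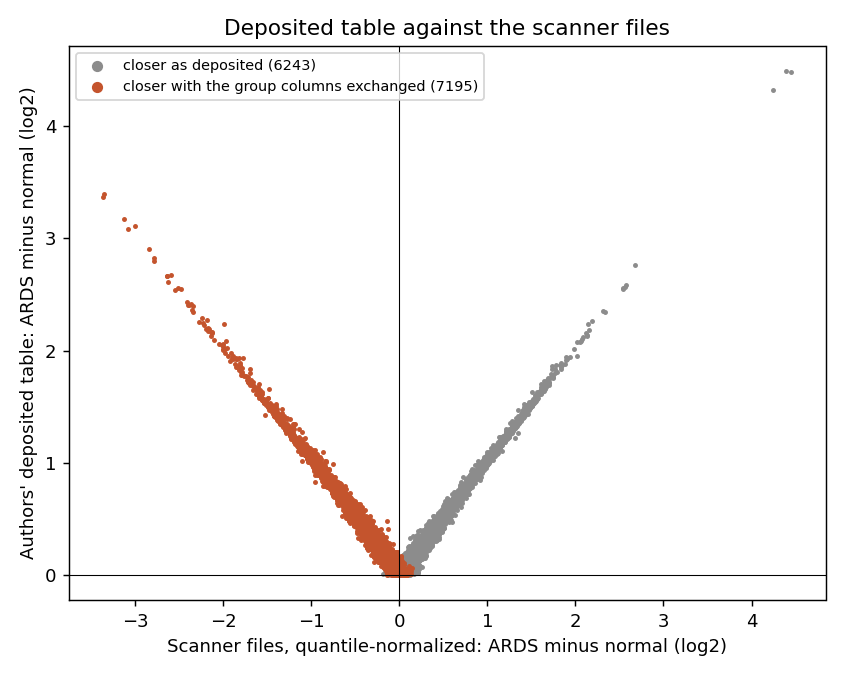
ARDS minus normal (log2) in the authors' deposited table (vertical) against the same difference in the quantile-normalized scanner signals (horizontal), 1 point per circRNA probe; orange marks the 7195 probes whose deposited values lie closer to the scanner values when the normal and ARDS columns are exchanged. The points form a V, with no deposited difference below 0.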

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

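All tests of explanations in this part were chosen after the results they bear on had been seen.

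The authors' deposited table drew attention because 100% of its 13438 probes had a higher mean in the ARDS columns, while 7203 of them were lower and 6235 higher in ARDS lung by the quantile-normalized scanner signals. A candidate explanation is that the normal and ARDS columns were exchanged for the probes that were lower in ARDS lung. For these probes the deviations of the deposited columns from their group mean, which do not depend on the difference between groups, correlated at 0.974 with those of the same-numbered arrays of the other group and at 0.334 with those of their own arrays, against 0.164 and 0.987 for the probes that were higher. A normalization that raised all ARDS values would keep each column in the order of its own array, yet the lowest rank correlation was 0.947 as deposited. How the exchange arose was not tested, and no biological explanation was tested, since both versions come from the same arrays.

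Of the control probes, eQC-41, which is a positive control, ranged over 4.78 log2 units between arrays, or 27.4-fold, from 5.81 in normal replicate 2 to 10.6 in normal replicate 1. The separate scan of ARDS replicate 3 cannot account for it, because the range within the first scan was already 4.78, and neither can array brightness, because the range was 5.28 after subtracting each array's 75th percentile. The groups did not part on it (difference 0.16, exact permutation p = 0.9, n = 3 each). RNA or label that carries other transcripts too may contribute. Within groups 459 circRNAs followed eQC-41 (limma), 447 of them rising with it. Of the 36 orders of its values within the groups 1 reached that number, with 433 as the highest of the others and 0 as the median. ARDS replicates 1 and 2 had nearly equal values, 9.857 and 9.802, so orders that exchange them hardly differ. In effect there are fewer than 36 orders, and they do not decide the matter. With eQC-41 as a covariate 4450 circRNAs passed in ARDS against normal lung, against 2604 without it.

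Other control probes that differed widely between arrays were E1A_r60_n11 with a range of 3.36 log2 units, eQC-42 with 3.05, ETG10_195139 with 2.69 and eQC-39 with 2.62. Like eQC-41, each was highest on normal replicate 1 and ARDS replicates 1 and 2. On these arrays E1A_r60_n11 was at 5.8, 5.26 and 4.87. It was at 3.13 and 4.01 in normal replicates 2 and 3, and at 2.44 in ARDS replicate 3. The cause of this shared pattern was not tested.

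The dimmer circRNA signal of the ARDS arrays was weighed as well. The separate scan cannot be its whole cause, because the 2 ARDS arrays of the first scan lay below all normal arrays, with a difference of -1.07 log2 units in the 75th percentile. If signal were proportional to RNA, less labelled RNA on every ARDS array alike would keep the share of signal in the 100 brightest probes. That share was 15 percentage points higher on ARDS arrays (39.4% ± 1.79 against 54.4% ± 3.3, SD, n = 3 each, with no overlap). Whether the brightest probes followed the amount of RNA in proportion was not tested, so less labelled RNA is not excluded. More linear RNA left on the ARDS arrays cannot be told apart from the group. The 10 linear probes brighter than 75% of circRNAs had a median scaled change of 0.54, with 7 higher. Without scaling these 10 ran from -1.78 for Actb to 0.12 for a probe without a symbol, so their rise was relative to the scaling. No measure of digestion was used here. A lower amount of most circRNAs in ARDS lung stays among the open explanations, as untested.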

How the results depend on the processing

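The deposited table set back and the eQC-41 covariate were chosen after seeing the data, and the linear transcripts were added after the files had been opened; the cause of the changes below was not tested unless stated. The count of 2604 circRNAs stayed within 1.5 times under quantile (2500) and median scaling (2712), normexp (1968, of which 828 higher), both filters, a trended and robust variance (3010), a fold of at least 2 with an unadjusted p (2813) and the scan block (3632). It was 7820 without scaling (33 higher, 7787 lower), 4089 with array weights (2282, 1807) and 4450 with the eQC-41 covariate (2805, 1645). The array weights were 8.08 for normal replicate 3 and 0.369 to 1.07 for the other arrays, so that fit leaned on 1 array. An unmoderated equal-variance test gave 48 after Benjamini-Hochberg (22, 26), and 2185 (1350, 835) at a fold of at least 2 and an unadjusted p under 0.05. The authors' deposited table gave 2343 higher and 0 lower as it stands (4888 with an unadjusted limma p under 0.05), and 975 higher of 2343 with the exchanged probes set back. As deposited ASCRPR013687 and ASCRPR000006 reversed to 3.11 and 3.37, and set back they were at -3.11 and -3.37. The set-back directions were fixed in advance, because probes were exchanged where that brought them closer to the scanner values. An exchange changes only the sign of a difference, so the count of 2343 could not change either. Setting back is therefore not a separate check of direction. Leaving out 1 array gave 3 to 3637 calls, 3 to 2071 higher and 0 to 1566 lower. In these fits 3298 to 6133 had an unadjusted p under 0.05. That 0 calls changed direction was fixed in advance, because the groups did not overlap for any call. For the same reason the named circRNAs kept their direction in all 24 such fits. They lost the threshold in 6, ASCRPR008416 in none.

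The median difference of 0.05 was -0.0655 with quantile, 0.0117 with median, -1.19 with no and -0.0194 with normexp scaling, 0.11 without a filter, 0.0243 with the scan block, 0.367 in the deposited table and -0.0544 with it set back; leaving out 1 array gave 0.0241 to 0.0839. The detection difference of -787 was -146.7 by the positive-and-significant flag, and -874.7 to -628.7 leaving out 1 array. The 18 linear transcripts became 7 with normexp, and 0 to 28 leaving out 1 array, with 21 to 32 at an unadjusted p under 0.05. Without scaling Rplp1 (-0.16), Gusb (-0.0632), Pop7 (-0.26), the custom Ldha probe (-0.22) and a probe without a symbol (-0.02) reversed.

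The values gave no clear sign that equal replicate numbers pair the arrays, but they cannot exclude it. Deviations from the group means correlated at 0.59, -0.23 and 0.14 for equal numbers, and normal replicate 2 correlated best with ARDS replicate 3 (0.55). With the replicate block 2907 circRNAs (1778 higher, 1129 lower) and 21 linear transcripts passed, the custom Ldha probe (limma adjusted p = 0.0558) not among them. Host gene tests and their alternatives were not run. Signal over background limits the dim circRNAs, 45 of the lower calls being bounds.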

Other observations

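The tests in this part were chosen after the data had been examined.

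Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many circRNA calls as the 2604 reported, and the highest of the other splits gave 243, when normal replicate 1 was grouped with ARDS replicates 1 and 2. With 10 splits the share cannot fall under 0.05, so these splits are too few to decide.

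Changes of circRNA probes with consecutive catalogue numbers were weakly related. Over 12426 such pairs the correlation of the log2 differences was 0.0452, above the 0.0414 that was the highest of 10000 shuffles (one-sided permutation p = 1e-04, the smallest they can give). At a distance of 2 numbers it was 0.012. There were 7 consecutive pairs in which both probes passed the test with a change of at least 4-fold, and in all 7 both moved in the same direction. A candidate explanation is that neighbouring probe numbers stand for related circRNAs, for example of 1 host gene, but the files do not pair the numbers with host genes.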
